A study of Mus musculus with 6 samples.

How the data were processed

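Bulk RNA sequencing of cultured mouse granulosa cells was compared between 3 control and 3 GSK4112 samples. Groups and replicate numbers were taken from the sample titles. The labels' protocols describe culture for 24 h, serum starvation for 12 h and treatment for 24 h with the medium changed every 12 h, while the design text of the series speaks of treatment in vivo. The samples are described here as cultured cells. The dose is left out because its unit in the labels is not a concentration.

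The deposited table holds FPKM values (fragments per kilobase of exon, normalized by the authors to library size) for 27151 Ensembl gene IDs in 6 columns, per the file headers. Each column was matched to its sample by name. Genome build GRCm38 is named in the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and values of genes with near-identical copies are uncertain. Symbols and coordinates came from GENCODE release M21 on GRCm38, in which 27098 of the IDs were found and 53 were not.

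Depth was read from the low values. FPKM multiplied by exon length gave steps that matched library totals of 18158271, 17260442 and 16638141 fragments in control replicates 1, 2 and 3. In GSK4112 replicates 1, 2 and 3 the totals were 16904493, 16559255 and 17382508. With these totals 92.8 to 93.1% of values below 500 fragments were whole within 0.01, and 90.4 to 90.7% of all values. At this depth a gene with 1 kb of exons gains 0.0551 to 0.0604 FPKM per fragment.

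Genes with a mean FPKM of at least 1 over the 6 samples were kept, which left 12181. They were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a trend in the variance, 2-sided, with a Benjamini-Hochberg adjusted p under 0.05 and no block. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Errors given with log2 changes are standard errors of limma. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, for the 33 of 36 lists with at least 5 members tested, adjusted over the lists. Camera with an estimated correlation was run beside it, and fry, which tests whether a set's genes move on balance in a single direction and not against other genes. No list was called with an estimated correlation, and fry called 2 lists, the mitochondrially encoded proteins and lipid uptake and transport. With an estimated correlation camera also uses only the residual degrees of freedom, which are few with 6 libraries. Lists with an estimated correlation near the preset 0.01 lost their calls too, such as granulosa identity (0.0175) and lipid uptake and transport (-0.0263). A call lost there thus does not by itself show that correlated members had made it. For single genes an exact permutation test of the 6 values cannot give a p below 0.1.

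Replicate numbers 1 to 3 occur in both groups. Whether they pair the samples was checked before the calls of the fits were compared. The deviations from the group means of same-numbered samples correlated at 0.665, 0.326 and 0.213 over genes, each over the limit of 0.1 set for pairing. The pairing thus comes from the data and not from a label, and for replicates 2 and 3 the correlations do not favour it. With the replicate 1 libraries apart in both groups, the others deviated together whatever their number. GSK4112 replicate 2 correlated better with control replicate 3 (0.53) than with control replicate 2, and GSK4112 replicate 3 better with control replicate 2 (0.357) than with control replicate 3. A fit with the replicate number as a block was run as an alternative.

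Before the data were examined, the lists, the tests, the alternatives and the rule for the genes named were fixed. The rule took 10 clock genes and the 5 most abundant genes. It took the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 in the higher group, groups that do not overlap and a symbol other than a predicted-gene name. From each list it took up to 3 called rises and 3 called falls, and the 2 most abundant members where fewer than 2 were called. It also took 11 genes of steroid synthesis, mitochondrial biogenesis and lipid transport. Genes chosen after their values were seen are said to be so. Some genes taken by the rule are not reported here.

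The alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, TPM scaling, median-of-ratios scaling, quantile normalization, rescaling without the 20 most abundant genes, limma without the trend, limma robust, sample weights, the replicate block, each replicate left out in turn, a fold limit of 2 and an adjusted p under 0.01. Added after the data were seen were leaving out both replicate 1 libraries, limma-voom on the recovered fragments, and the block combined with these or with other scalings. Transcripts of the mitochondrially encoded mRNAs were compared with all other transcripts of GENCODE M21 with blastn 2.17.0+ at 95% identity or more.

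The gene test was tested on simulated data, in which 200 of 12091 genes of the comparison of GSK4112 with control were changed. Without the block it recovered 1.5% of 67 genes changed 1.5-fold, 49.3% of 67 changed 2-fold and 84.8% of 66 changed 3-fold, with 1 call among unchanged genes (1.1% of calls). With the block it recovered 17.9%, 88.1% and 95.5%, with 9 calls among unchanged genes (6.3%). The simulated libraries were built with the replicate effects and residual spread of the block fit. The higher recovery with the block was thus built in and does not favour that fit. In the same simulation camera called the shifted list and 0 of 30 unchanged lists. The unchanged lists were random genes with independent residuals. They do not measure false calls for lists whose members move together, such as mitosis (estimated correlation 0.9914). Figures were drawn with matplotlib 3.10.9.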

Results

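RNA was sequenced from mouse ovarian granulosa cells, the somatic cells that surround the oocyte and make steroid hormones. The cells were taken by puncture of follicles, cultured for 24 h, starved of serum for 12 h and then kept for 24 h with or without GSK4112. GSK4112 is a small-molecule agonist of NR1D1 (REV-ERBα), a heme-binding nuclear receptor that represses transcription in the circadian clock. There were 3 control and 3 GSK4112 libraries, and values below are mean ± SD of FPKM with n = 3 per group, control first. The labels do not say whether the libraries came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The FPKM steps implied 16559255 to 18158271 fragments per library, and 12012 to 12290 genes per library had an FPKM of at least 1. The 5 most abundant genes held 8.2% of the summed FPKM. They were mt-Co1 (11209 ± 874 and 11887 ± 902), mt-Nd1 (3794 ± 243 and 2925 ± 13.2), Gm23935 (3396 ± 2802 and 3065 ± 1069), Eef1a1 (2766 ± 155 and 3259.5 ± 201) and mt-Cytb (3474 ± 240.2 and 2529 ± 93.5). Gm23935 is annotated as a microRNA gene (chromosome 16, 11144125 to 11144181, plus strand). FPKM is per kilobase, so a gene this short ranks high with fewer fragments than the others.

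**Figure D1:**
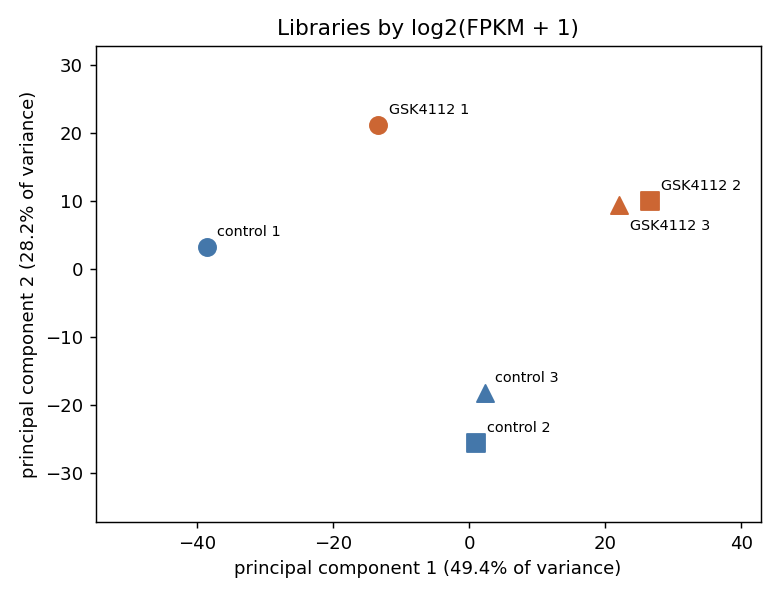
Principal components of log2(FPKM + 1) over the genes tested, with the share of variance on each axis; colours mark the groups and shapes the replicate numbers. The replicate 1 libraries have the lowest values of component 1 (control -38.59, GSK4112 -13.38), and component 2 is -25.59 and -18.24 in control replicates 2 and 3 and at least 9.43 in the GSK4112 libraries.

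The libraries with replicate number 1 stood apart in both groups. On the component that held 49.4% of the variance, control replicate 1 lay at -38.59 and GSK4112 replicate 1 at -13.38, while the other 4 libraries lay between 1.05 and 26.56. The summed FPKM of 28 mitosis genes was 388 in control replicate 1 and 293 in GSK4112 replicate 1. It was 94.7 and 104 in the other control libraries and 59.8 and 52.6 in the other GSK4112 libraries. Markers of theca and ovarian stroma summed to 285 and 181 in the replicate 1 libraries and to between 69.9 and 106 in the rest. Most of the replicate 1 sums came from a single gene, Acta2 (234 in control and 125 in GSK4112), which is also in the list of TGF-beta and YAP targets. The replicate 1 libraries deviated together from their group means (correlation 0.665). GSK4112 replicates 2 and 3 correlated at 0.326 and 0.213 with their own number in control. With the other number they correlated at 0.53 and 0.357. The comparison was also fitted with the replicate number as a block, a pairing that no label gives. The value with the block is given where it changes a call. Genes named in parentheses after a count of 5 or fewer were chosen after their values were seen.

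The first question was whether the clock genes on which the receptor acts differed after agonist treatment. None of 20 measured members of the clock list was called, nor when adjusted over the list alone, and 2 were higher with the replicate block. Nr1d1 itself (ENSMUSG00000020889; GRCm38 chromosome 11, 98767932 to 98775333, minus strand) was at 9.06 ± 0.362 and 11.8 ± 0.279, a log2 difference of 0.34 ± 0.0742 (SE) with an adjusted p of 0.0911 in limma. Its GSK4112 values all lay above its control values, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. That separation was common, since the groups did not overlap in 2872 of 12181 genes tested (23.6%, with 10% by chance). Its paralog Nr1d2 was at 15.7 ± 6.26 and 21.1 ± 3.99 (adjusted p = 0.4928). Arntl, which encodes the clock activator BMAL1 and is a direct target of REV-ERB repression, was at 1.51 ± 0.122 and 1.34 ± 0.34 (adjusted p = 0.7499). Clock (6.94 ± 0.473 and 7.32 ± 1.16), Per1 (6.11 ± 0.537 and 6.096 ± 0.692), Per2 (2.39 ± 0.437 and 2.27 ± 0.084) and Cry1 (4.699 ± 0.236 and 4.44 ± 0.161) were not called. The same held for Nfil3 (10.7 ± 0.212 and 12.2 ± 0.809), Dbp (5.34 ± 3.07 and 9.08 ± 2.94) and the kinase genes Csnk1d (50.6 ± 2.998 and 52.4 ± 3.65) and Csnk1e (18.1 ± 0.306 and 19.6 ± 0.963). Npas2 was below the filter on low values (0.13 ± 0.087 and 0.358 ± 0.239). The clock list as a set was not called (median log2 change 0.14, adjusted p = 0.3673).

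Of 7 measured genes that REV-ERB proteins repress in other tissues, none was called over all genes and Nr1d1 was higher when adjusted over the list alone, and 1 was higher with the block. Lpl, lipoprotein lipase, was at 15.5 ± 7.05 and 12.7 ± 8.85 (adjusted p = 0.7268), and the set was not called (adjusted p = 0.6372).

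Over all genes, the falls with GSK4112 included Ccl17, Bmp3, Col8a1 and Ahr, and the rises included Smoc2, Mt1, Slc27a6 and Xdh. Of 12181 genes tested, 126 changed, 50 higher and 76 lower; with sample weights 830 did, 470 higher and 360 lower, so the share of rises depends on the fit. Among them, 18 rises and 43 falls were at least 2-fold on the log2(FPKM + 1) scale. The largest fall among the genes named by the rule was that of Ccl17, a chemokine (chromosome 8, 94810453 to 94812036, plus strand), from 34.9 ± 9.399 to 4.45 ± 3.45 (log2 change -2.87 ± 0.42 SE, adjusted p = 0.0421). Bmp3, a ligand of the TGF-beta family (chromosome 5, 98854415 to 98884396, plus strand), fell from 6.08 ± 0.748 to 0.866 ± 0.099 (-1.92 ± 0.12, adjusted p = 0.0088). The collagen genes Col8a1 (81.6 ± 9.85 to 18.5 ± 6.37, adjusted p = 0.0187) and Col10a1 (7.06 ± 1.49 to 1.19 ± 0.138, adjusted p = 0.0111) also fell. So did the matrix proteoglycan gene Ogn (10.7 ± 2.32 to 1.91 ± 1.21) and the collagen receptor subunit gene Itga2 (8.16 ± 1.03 to 2.15 ± 0.117). Ahr, the ligand-activated receptor for dioxins, fell from 34.8 ± 7.02 to 10.3 ± 0.717 (adjusted p = 0.0111). Other falls were those of the growth factor gene Pdgfb (29.8 ± 5.99 to 10.3 ± 2.995), the small GTPase gene Gem (10.5 ± 2.36 to 2.51 ± 0.359), Arxes2 (30.98 ± 7.24 to 7.61 ± 0.663) and Smtnl2 (15.8 ± 4.49 to 5.08 ± 0.968).

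The largest rise among the genes named by the rule was that of Smoc2, a secreted matricellular protein (chromosome 17, 14279506 to 14404790, plus strand), from 11.2 ± 2.05 to 39.4 ± 11.2 (log2 change 1.70 ± 0.24 SE, adjusted p = 0.04). Mt1, a metallothionein, rose from 139 ± 38.96 to 395 ± 41.3 (adjusted p = 0.0356). Cybrd1, a ferric reductase, rose from 1.78 ± 0.31 to 7.51 ± 1.46 (adjusted p = 0.0154) and Slc40a1, the iron exporter ferroportin, from 18.9 ± 3.703 to 40.6 ± 3.09 (adjusted p = 0.0368). Xdh, xanthine dehydrogenase of purine breakdown, rose from 5.25 ± 0.625 to 14.96 ± 0.682 (1.36 ± 0.0995, adjusted p = 0.0088). Slc27a6, a fatty acid transport protein, rose from 3.79 ± 0.805 to 12.4 ± 2.902, and Gpnmb, a glycoprotein of lysosomes and melanosomes, from 9.67 ± 3.43 to 28.6 ± 1.69. Other rises were those of Trib3 (2.73 ± 0.579 to 9.37 ± 1.36), the mitochondrial sulfurtransferase gene Tst (79.6 ± 6.25 to 182 ± 28.6), Reep1 (8.701 ± 2.66 to 21.9 ± 0.411), Jade1 (27.5 ± 3.57 to 61.3 ± 10.1) and Fam114a1 (11.1 ± 0.975 to 24.7 ± 0.916). With the replicate block 839 genes were called, 374 higher and 465 lower, and all 126 were among them in the same direction; median-of-ratios scaling gave 39 higher and 105 lower, and leaving out both replicate 1 libraries gave 856. Leaving out control replicate 2 left 8 calls in limma, and leaving out control replicate 3, GSK4112 replicate 2 or GSK4112 replicate 3 left 0 (1843, 1224 and 1318 genes at an unadjusted p under 0.05).

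**Figure D2:**
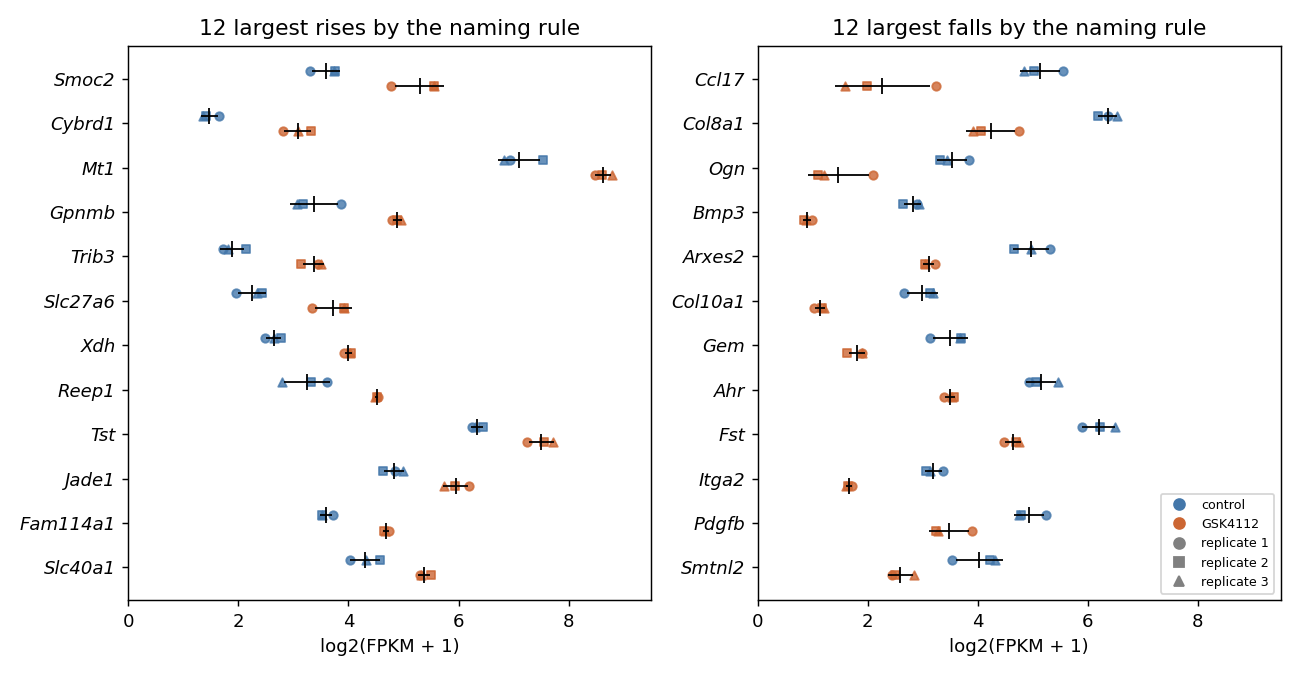
Expression of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) among those the naming rule takes, as log2(FPKM + 1) on the horizontal axis; points are single libraries, the short vertical mark is the group mean and the bar its SD (n = 3). By that rule, the control values and the GSK4112 values of each do not overlap.

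The title and design text put the endocrine function of granulosa cells at the centre of the study. Hsd17b1, which converts estrone to estradiol (chromosome 11, 101078411 to 101080527, plus strand), fell from 64.3 ± 7.25 to 25.3 ± 3.94 (log2 change -1.32 ± 0.14 SE, adjusted p = 0.0187). Fst, which encodes the activin-binding protein follistatin (chromosome 13, 114452290 to 114458951, minus strand), fell from 73.6 ± 15.4 to 24.01 ± 2.38 (-1.56 ± 0.16, adjusted p = 0.0187). Of 15 measured genes of steroid synthesis, 1 fell and 14 did not pass. Adjusted over the list alone 2 fell (Cyp11a1 and Hsd17b1), and 2 fell with the block (Akr1c18 and Hsd17b1). Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, was at 751 ± 171 and 418 ± 28.98 and missed the threshold (adjusted p = 0.1029). Star, which carries cholesterol into mitochondria, was at 42.2 ± 18.9 and 51.5 ± 10.1 (adjusted p = 0.6082) and Hsd3b1 at 2188 ± 1053 and 2072 ± 786 (adjusted p = 0.9946), and their groups overlapped. Cyp19a1, the aromatase gene, was under the filter in both groups (0.073 ± 0.071 and 0.086 ± 0.076). The list was lower as a set (median -0.11, adjusted p = 0.017 in camera), with an adjusted p = 0.8826 with an estimated correlation. The call ended without a filter (0.1662), under TPM scaling (0.0665), with the block and quantile scaling (0.0551) and without control replicate 2 (0.1381). Over the alternatives its adjusted p ran from 3.19e-04 to 0.1662.

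Of 25 measured genes of granulosa identity and hormone receptors, 2 fell (Fst, and Hsd17b1 of the steroid list). Adjusted over the list alone 3 rose and 9 fell, and with the replicate block 3 rose and 7 fell. Among these, chosen after their values were seen, were the genes of the inhibin and activin subunits Inhba (335 ± 31.9 and 124 ± 71.7, adjusted p = 0.1018 without and 0.0266 with the block) and Inhbb (14.3 ± 6.07 and 4.21 ± 2.83, 0.1257 and 0.0018). Kitl, the granulosa ligand for the oocyte's KIT receptor, was higher with the block (34.5 ± 6.79 and 79.1 ± 16.04, 0.0549 and 0.0257). The list was called lower (median -0.11, adjusted p = 0.0171; adjusted p = 0.6716 with an estimated correlation). That call ended under median-of-ratios (0.0542) and quantile scaling (0.0535), and under both with the block (0.0555 and 0.0551). It also ended without control replicate 3 (0.0769) and without GSK4112 replicate 1 (0.0763). Without both replicate 1 libraries it ended too (0.0621), but not with the block (0.0185). With a mean FPKM of at least 5 or without both replicate 1 libraries the median turned to 0.0506 and 0.0092 (range of the adjusted p 0.0081 to 0.0769).

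The title of the series names mitochondrial biogenesis. Of 24 measured regulators of it none was called, with or without the block or adjusted over the list alone, and the set was not called (median 0.0051, adjusted p = 0.7183). Nrf1 was at 3.83 ± 0.091 and 3.82 ± 0.41 and Tfam, the mitochondrial transcription factor, at 10.1 ± 0.425 and 9.57 ± 0.599. The import genes Timm23 and Tomm20 were at 49.6 ± 6.38 and 48.5 ± 3.43 and at 40.6 ± 1.74 and 43.7 ± 1.87. Ppargc1a, which encodes the coactivator PGC-1α, was below the filter (0.059 ± 0.023 and 0.14 ± 0.042). Of 75 nuclear genes for the respiratory chain and ATP synthase none was called, also adjusted over the list alone (set adjusted p = 0.2496), including Cox6a1 (415 ± 43.7 and 480.2 ± 38.4) and Atp5b (256 ± 20.9 and 236 ± 13.5). That set was called as lower without control replicate 3 (0.0027) and without GSK4112 replicate 3 (0.0101; range 0.0027 to 0.9202). Camera sets a list against all other genes, whose median was 0.0543, so its direction was lower for the biogenesis and respiratory chain lists although their medians (0.0051 and 0.0034) lay above 0.

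The mRNAs encoded by the mitochondrial genome were lower as a set, with 11 of 12 measured members below control (median -0.36, adjusted p = 4.51e-06 in camera and 0.0312 in fry; adjusted p = 0.6557 with an estimated correlation and 0.0774 in fry with the block). Of the 12, 1 fell over all genes, 6 adjusted over the list alone, and 3 with the block (mt-Atp6, mt-Co2 and mt-Nd4l). The member that fell was mt-Co2 (66.2 ± 3.88 to 44.9 ± 1.95, adjusted p = 0.0423). The genes mt-Co2, mt-Atp6, mt-Nd4l and mt-Co1, the member that was not lower, match transcripts of other genes at 95% identity or more over their whole length or nearly so, and their values are uncertain. The same holds for mt-Co3 (99.9% of its length) and mt-Nd3 (99.1%). A part of the length is matched in mt-Nd4 (63.6%), mt-Nd5 (52.3%) and mt-Nd2 (49.1%). Without any such match were mt-Nd6, mt-Nd1 (3794 ± 243 and 2925 ± 13.2, adjusted p = 0.2798) and mt-Cytb (3474 ± 240.2 and 2529 ± 93.5, adjusted p = 0.2006).

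**Figure D3:**
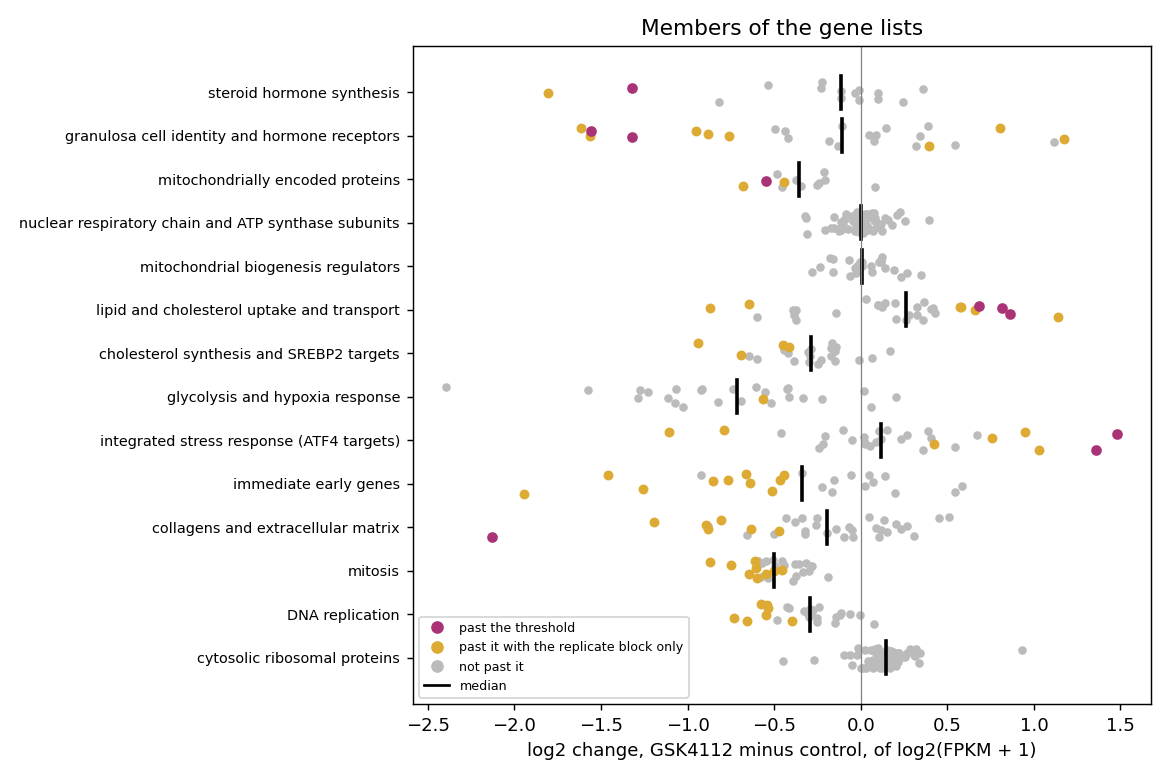
Log2 change of each measured member of 14 gene lists, GSK4112 minus control on the log2(FPKM + 1) scale; coloured points passed an adjusted p of 0.05 without or only with the replicate block, and black bars are list medians. The medians run from -0.71 for glycolysis and hypoxia to 0.26 for lipid uptake and transport.

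Lipid transport, the other process in the title, held genes that rose. In the list of lipid and cholesterol uptake and transport, 3 of 31 measured members rose and 28 did not pass, and adjusted over the list alone 9 rose and 3 fell (Fabp5, Gramd1b and Soat1). With the block 7 rose and 2 fell (Fabp5 and Gramd1b). Lrp8, a receptor for apolipoprotein E and reelin, rose from 5.78 ± 0.495 to 11.3 ± 0.727 (log2 change 0.86 ± 0.0932 SE, adjusted p = 0.0202). Abca1, the cholesterol efflux pump, rose from 3.43 ± 0.508 to 6.796 ± 0.843 (adjusted p = 0.0481) and Npc1, which moves cholesterol out of lysosomes, from 9.24 ± 0.602 to 15.5 ± 1.301 (adjusted p = 0.0377). The uptake genes Scarb1 (80.03 ± 8.53 and 72.6 ± 10.1) and Cd36 (2.03 ± 1.56 and 2.48 ± 0.996) were not called. The set was higher (median 0.26, adjusted p = 0.0231 in camera and 0.0031 in fry; adjusted p = 0.6557 with an estimated correlation). In camera it was not called with the replicate block (0.0579), with a mean FPKM of at least 5 (0.1034), without control replicate 3 (0.0719), without GSK4112 replicate 1 (0.0763) or without both replicate 1 libraries (0.1242; range 0.0095 to 0.1242). In fry the set stayed called with the block (adjusted p = 0.0271).

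Of 24 measured genes of cholesterol synthesis and its regulator SREBP2, 22 were below control but none was called over all genes or adjusted over the list alone. As a set they were lower (median -0.29, adjusted p = 9.46e-06; adjusted p = 0.8826 with an estimated correlation). The replicate 1 libraries held the highest sums in each group, and without control replicate 1 the median shrank to -0.0939 (adjusted p = 0.0072), and without both replicate 1 libraries it was -0.28 (1.07e-05; range 1.50e-08 to 0.0072). With the block 4 members fell, and 11 adjusted over the list alone. Among the 4, chosen after its values were seen, was Sc5d (16.4 ± 3.58 and 9.72 ± 1.62, adjusted p = 0.1239 without and 0.0134 with the block), which acts late in the pathway. Srebf2, the gene of SREBP2, was at 43.6 ± 3.13 and 35.4 ± 1.25 (adjusted p = 0.1558) and Scap, its escort protein, at 66.6 ± 3.98 and 75.2 ± 7.13.

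None of the remaining lipid lists was called. Fatty acid and triglyceride synthesis (20 measured members, adjusted p = 0.303) had 0 calls, 1 fall adjusted over the list alone (Fads2) and 2 falls with the block (Fads2 and Pparg), with Me1 at 676 ± 208 and 621 ± 114 and Scd2 at 237 ± 35.7 and 264 ± 50.1. Fatty acid oxidation (23 members, 0.6372) had 0 calls in both and 1 rise with the block (Pdk4), with Cpt1a at 118 ± 18.4 and 145 ± 10.04 and Acaa2 at 59.3 ± 7.697 and 68.8 ± 1.57. Lipid droplet proteins and lipolysis (10 members, 0.3426) had 0 calls, 3 rises adjusted over the list alone (Abhd5, Plin3 and Plin4) and 1 with the block (Abhd5), with Plin3 at 60.9 ± 3.65 and 83.4 ± 7.21 and Pnpla2 at 33.3 ± 2.16 and 34.3 ± 4.79.

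Among stress pathways, the ATF4 targets held single genes that rose. Trib3 and Aldh1l2, a mitochondrial folate enzyme (0.785 ± 0.165 to 3.67 ± 1.28, adjusted p = 0.046), were the 2 of 29 measured ATF4 targets of the integrated stress response that rose. Adjusted over the list alone 7 rose and 2 fell (Cth and Nupr1), and with the block 6 rose and 2 fell (Cth and Nupr1). That list was not called as a set (median 0.12, adjusted p = 0.1928) except without a filter (0.0154), with the block and median-of-ratios (0.0332) or quantile scaling (0.0378) and without GSK4112 replicate 2 (0.017; range 0.0154 to 0.6922). Of 20 genes of the endoplasmic reticulum's unfolded protein response none was called, including the chaperones Calr (369 ± 73.9 and 295 ± 12.8) and Pdia3 (310.1 ± 42.5 and 265 ± 3.84), and 1 rose (Herpud1) and 2 fell (Pdia4 and Pdia6) adjusted over the list alone. With the block 1 rose (Herpud1) and 2 fell (Manf and Pdia6). The set was lower (median -0.20, adjusted p = 0.017; adjusted p = 0.8826 with an estimated correlation). The call was lost without control replicate 1 (median -0.0249, adjusted p = 0.3522), without GSK4112 replicate 3 (0.0507) and without both replicate 1 libraries (0.0788; range 3.12e-04 to 0.3522).

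None of 27 NRF2 antioxidant genes was called over all genes, and 4 rose (Cbr3, Fth1, Ftl1 and Nqo1) and 1 fell (Gpx1) adjusted over the list alone. With the block 3 rose (Cbr3, Ftl1 and Gsta4) and 1 fell (Gpx1). Fth1, the ferritin heavy chain, was at 779.5 ± 105 and 1304 ± 98.6 (adjusted p = 0.0734) and Me1, malic enzyme, at 676 ± 208 and 621 ± 114. The NRF2 set was not called (adjusted p = 0.0717), but was higher with the block (0.0435; adjusted p = 0.8706 with the block and an estimated correlation). It was also called without control replicate 2 (2.59e-04), without GSK4112 replicate 2 (0.0207), without a filter (0.0126) and under TPM (0.0213) and quantile scaling (0.0304; range 2.59e-04 to 0.5387). Of 25 p53 targets and apoptosis genes none was called, also adjusted over the list alone (set adjusted p = 0.6372), with Cdkn1a at 68.9 ± 9.32 and 71.2 ± 3.45 and Mcl1 at 74.9 ± 4.41 and 61.4 ± 0.857. With the block 2 of them rose (Bcl2l11 and Bid) and 2 fell (Btg2 and Perp).

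None of 26 measured genes of glycolysis and hypoxia was called, with or without adjustment over the list alone, and 1 fell with the block (Adm). Yet 23 lay below control and the set was lower (median -0.71, adjusted p = 9.46e-06; adjusted p = 0.8826 with an estimated correlation). The list summed to 4837 FPKM in control replicate 2, against 1347 and 1348 in the other control libraries and 1024 to 1232 in GSK4112. Pkm was at 304 ± 160.4 and 209 ± 23.3 and Aldoa at 304 ± 212 and 179 ± 12.5. Without control replicate 2 the median was -0.16 (adjusted p = 0.0047; range over the alternatives 5.82e-16 to 0.0047).

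**Figure D4:**
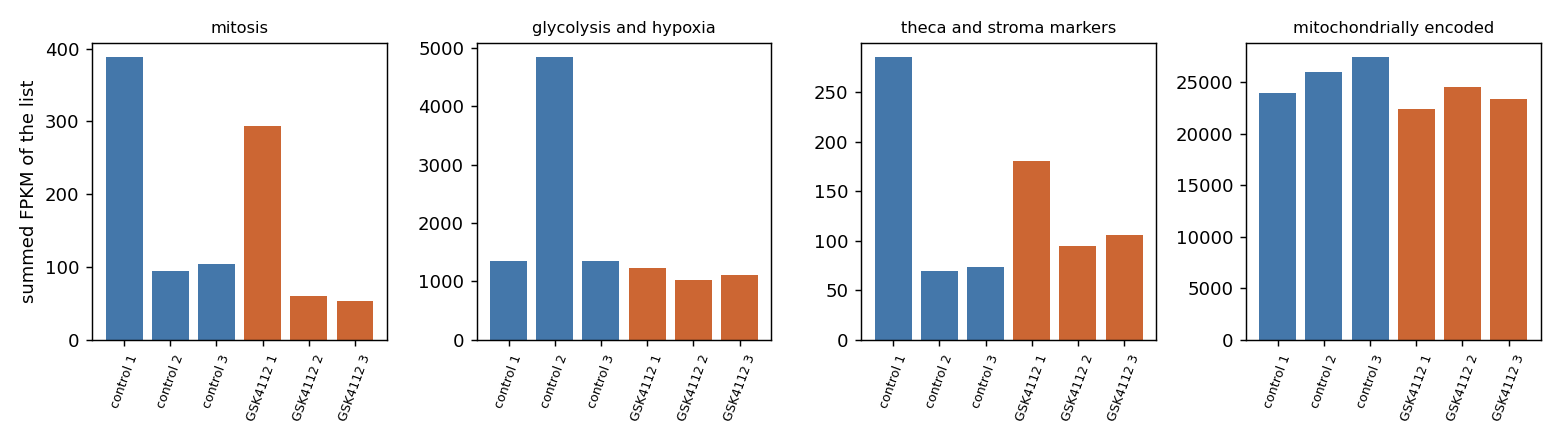
Summed FPKM of 4 gene lists in each library, with bars from 0, for control (blue) and GSK4112 (orange). The mitosis sum is 388 in control replicate 1 and 293 in GSK4112 replicate 1, and the glycolysis and hypoxia sum reaches 4837 in control replicate 2.

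All 28 measured mitosis genes and 27 of 28 DNA replication genes were below control, yet none was called over all genes or adjusted over the list alone. Their sums were highest in the replicate 1 libraries, while replicates 2 and 3 stood in opposite order in control and in GSK4112. With the block 9 mitosis genes and 7 replication genes fell, and 24 and 14 adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, was at 23.4 ± 21.2 and 14.7 ± 13.2 (adjusted p = 0.7086 without and 0.0147 with the block). Mcm7, a subunit of the replicative helicase, was at 23.8 ± 5.55 and 17.7 ± 3.03 (0.3374 and 0.0494). Ccnb2 (16.7 ± 14.4 and 11.2 ± 10.2) and Pcna (33.5 ± 11.9 and 35.2 ± 11.3) were called in neither fit. As sets mitosis (median -0.50, adjusted p = 0.0029) and DNA replication (-0.30, adjusted p = 0.0015) were lower, each with an adjusted p = 0.8826 with an estimated correlation; in fry DNA replication was called only with the block (adjusted p = 0.7179 without and 0.0271 with it). Without control replicate 1 their medians turned to 0.0725 and 0.0154 (adjusted p = 0.5955 for both), but that leaves in GSK4112 replicate 1; without both replicate 1 libraries (1.39e-15 and 1.23e-07) and with the block (1.14e-15 and 2.99e-10) both stayed called. Without GSK4112 replicate 3 the adjusted p was 0.1782 and 0.0519, and mitosis was also not called without GSK4112 replicate 2 (0.0738). Over the alternatives the adjusted p ran from 1.14e-15 to 0.5955 for mitosis and from 2.99e-10 to 0.5955 for replication.

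In the list of collagens and extracellular matrix, Col8a1 was the 1 of 35 measured members that fell, 3 fell adjusted over the list alone (Col8a1, Plod2 and Thbs1), and 7 fell with the block. Thbs1, thrombospondin 1, was at 1226 ± 314 and 523 ± 23.98 (adjusted p = 0.0539 without and 0.0194 with the block), and Sparc at 532 ± 35.03 and 513 ± 36.7. None of 19 TGF-beta and YAP targets was called, nor adjusted over the list alone, and with the block 1 rose and 4 fell (Amotl2, Ccn1, Inhba and Myl9). Ccn1 was at 346 ± 134 and 200.3 ± 138 (0.3826 without and 0.029 with the block) and Axl at 274 ± 43.04 and 289.6 ± 49.4. Both sets were lower (matrix median -0.20, adjusted p = 0.0015; TGF-beta and YAP -0.18, adjusted p = 0.0427), each with an adjusted p = 0.8826 with an estimated correlation. Without control replicate 1 the matrix median turned to 0.0715 (adjusted p = 0.338) and the TGF-beta and YAP median to 0.13 (0.8166). Without both replicate 1 libraries both stayed called (medians -0.0773 and -0.18, adjusted p = 0.0291 and 0.0139). The TGF-beta and YAP call also ended without GSK4112 replicate 2 (0.225) or 3 (0.1782), without a filter (0.0733), with a mean FPKM of at least 5 (0.1298) and under median-of-ratios (0.1042) and quantile scaling (0.1201). Over the alternatives the adjusted p ran from 1.78e-04 to 0.8166, and for matrix genes from 4.70e-05 to 0.338.

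Of 23 immediate early genes none was called over all genes, 5 fell adjusted over the list alone (Egr1, Fosb, Ier3, Myc and Nr4a1), and 10 fell with the block. Ier3 was at 227 ± 32.5 and 135 ± 37.6 (adjusted p = 0.1436 without and 0.045 with the block) and Fosl2 at 129.7 ± 37.9 and 139 ± 20.4. Egr1 (21.1 ± 9.69 and 7.12 ± 3.85, 0.1374 and 0.0018) and Fosb (4.002 ± 1.64 and 1.09 ± 0.675, 0.1097 and 0.0053), which encode transcription factors, were added after their values were seen. The set was lower (median -0.34, adjusted p = 0.0015; adjusted p = 0.8826 with an estimated correlation). The replicate 1 libraries held the highest sums in each group, and without control replicate 1 the median shrank to -0.12 (adjusted p = 0.0139), and without both replicate 1 libraries it was -0.44 (3.48e-06; range 1.67e-06 to 0.0139).

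Of 73 measured cytosolic ribosomal protein genes 66 lay above control and none was called, also adjusted over the list alone. Rplp1 was at 1005 ± 136 and 1125 ± 113 and Rplp0 at 856 ± 73.99 and 961 ± 77.98. The set was higher (median 0.15, adjusted p = 0.0015; adjusted p = 0.8826 with an estimated correlation), and not called without control replicate 3 (0.2813) or GSK4112 replicate 3 (0.1782; range 4.30e-08 to 0.2813). In all, 13 of 33 tested lists were called, 2 higher and 11 lower, and 0 with an estimated correlation, where few degrees of freedom make a call hard to reach. Other splits of the 6 libraries called 4 to 19 lists.

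Markers of other cells did not separate the groups as sets. Theca and stroma (8 measured members, adjusted p = 0.9297) and leukocytes (5 members, 0.8731) were not called, with 0 and with 1 higher (Cd68) and 1 lower member (Fcgr3) adjusted over the list alone. With the block 1 leukocyte marker fell (Fcgr3). Epithelium (7 members, 0.285) was not called except without a filter (0.037; range 0.037 to 0.6317). Of its members 1 rose (Epcam) and 1 fell (Krt18) adjusted over the list alone, and 1 rose (Epcam) and 2 fell (Krt18 and Krt8) with the block. Acta2 was at 109 ± 109 and 88.7 ± 32.5, Col1a1 at 13.6 ± 10.9 and 9.26 ± 3.72, and the macrophage genes Lyz2 and Cd68 at 16.1 ± 15.9 and 17.8 ± 10.6 and at 3.11 ± 1.197 and 5.26 ± 0.612. The epithelial keratin genes Krt8 (37.3 ± 25.4 and 12.5 ± 8.21, adjusted p = 0.2494 without and 0.0038 with the block) and Krt18 (30.7 ± 12.2 and 9.95 ± 4.25, 0.0934 and 0.0018) were called as lower with the block, and also without both replicate 1 libraries. No marker of endothelium, oocytes or red blood cells reached a mean FPKM of 1. The most abundant were Eng (0.746 ± 0.204 and 0.945 ± 0.45) and Robo4 (0.53 ± 0.16 and 0.393 ± 0.071) of endothelium, Kit (0.463 ± 0.066 and 0.735 ± 0.12) and Padi6 (0.529 ± 0.917 and 0.315 ± 0.205) of oocytes and Alas2 (0.162 ± 0.083 and 0.19 ± 0.177) of red blood cells. Hba-a1 was listed at 0 in the GSK4112 libraries and at 0, 0.143 and 0 in the control libraries.

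The remaining lists were not called. Of 13 ovulation and luteinization genes (adjusted p = 0.1816) 1, Cyp11a1, fell adjusted over the list alone, 2 fell with the block (Akr1c18 and Ptgs2), and Adamts1 was at 60.5 ± 13.8 and 47.5 ± 6.29. That list was called as lower without control replicate 1 (0.0072), with sample weights (0.0247) and without both replicate 1 libraries (0.0026; range 0.0022 to 0.597). Of 74 mitochondrial ribosome genes (0.0569) none was called in either way, with Mrpl34 at 82.1 ± 13.2 and 81.999 ± 10.3 and Mrps21 at 48.2 ± 5.55 and 51.4 ± 2.79. The set was called as lower under median-of-ratios (0.0159) and quantile scaling (0.0421), without control replicate 3 (0.0047) and without GSK4112 replicate 3 (0.0104; range 0.0047 to 0.7535). Mitochondrial fusion, fission and mitophagy (25 members, 0.6372) had 0 calls and 1 rise with the block (Optn), with Sqstm1 at 302 ± 77.3 and 440.2 ± 42.6 and Gabarap at 96.96 ± 14.8 and 133 ± 5.09. Inflammatory cytokines and chemokines (13, 0.9297) had 0 calls, and 1 rise (Csf1) and 1 fall (Ptgs2) with the block, with Ptges at 75.2 ± 25.9 and 72.6 ± 15.02 and Cxcl12 at 27.8 ± 4.63 and 36.03 ± 4.32. Of 11 interferon-stimulated genes (0.8871) 1 rose adjusted over the list alone (Oasl2) and 1 with the block (Oasl2), with Bst2 at 163 ± 17.1 and 133 ± 5.31 and Ifitm3 at 5.73 ± 1.799 and 5.06 ± 0.833. Of 15 genes of xenobiotic metabolism (0.6372) Ahr fell, and 3 rose (Abcc4, Ahrr and Nqo1) and 1 fell (Ahr) adjusted over the list alone. With the block 4 rose (Abcc4, Ahrr, Cyp1b1 and Gsta4) and 1 fell (Ahr). Gstm1 was at 275 ± 162 and 343 ± 154 and Cyp1b1, a target of the receptor encoded by Ahr, at 89.4 ± 39.3 and 137 ± 57.8 (adjusted p = 0.5464 without and 0.0163 with the block). Of 16 genes of heme synthesis and turnover (0.7045) 1 rose adjusted over the list alone (Uros), with Hmox1 at 80.9 ± 59.3 and 106 ± 16.8 and Cpox at 44.1 ± 2.2 and 40.7 ± 11.2. Median and mean differed in sign for interferon-stimulated genes (-0.13 and 0.0031) and for theca and stroma markers (-0.0026 and 0.0989), and the inflammatory list had a median of 0.0806 but lay below the other genes in camera.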

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

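Among the alternatives, leaving out both replicate 1 libraries, the voom fits and the block combined with another scaling were chosen after seeing the data. For 167 genes named or taken by the rule the 24 alternatives gave 3988 values, of which 3267 kept direction and side of the threshold, 445 gained a call, 194 lost one and 82 turned direction (0 of them of a called gene). For 33 lists the alternatives other than the voom fits, which ran no list test, gave 722 values. Of these 621 kept both, 22 gained and 31 lost a call and 48 turned (7 of a called list). The count of 126 genes was 119 and 125 with pseudocounts of 0.1 and 0.5, 132 with a mean FPKM of at least 5, 144 under median-of-ratios scaling, 155 under quantile normalization, 137 rescaled without the 20 most abundant genes, 112 without the trend and 128 in the robust fit. It was 26 without a filter (21 of them among the 126), 70 under TPM scaling, 61 at 2-fold or more, 6 at an adjusted p under 0.01, 830 with sample weights, 166 in voom and 856 without both replicate 1 libraries. The replicate block gave 839 genes, and 786 with median-of-ratios scaling (240 higher and 546 lower), 769 with quantile normalization, 1139 without both replicate 1 libraries and 1338 in voom. Leaving out single replicates gave 0 to 153 genes. Called lists numbered 9 to 15 over the refits, 0 with an estimated correlation and 2 in fry. Of the agonist target genes 0 were called, except 1 with sample weights. Beyond the calls given with the results, the block changed no other call of the lists in camera or fry. The causes of these shifts were not tested. Leaving out a library leaves fewer samples, and dropping the filter tests more genes. Fewer samples alone do not set the count, which was 138 without control replicate 1 and 153 without GSK4112 replicate 1. Depth limits genes near 1 FPKM: 1 fragment per kb is 0.0551 to 0.0604 FPKM.

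With a pseudocount of 0.1 the direction turned for the list theca and stroma markers (0.0231). With a pseudocount of 0.5 the direction turned for the list theca and stroma markers (0.0068). Without a filter the direction turned for the list theca and stroma markers (0.0695). With a mean FPKM of at least 5 the direction turned for the lists granulosa cell identity and hormone receptors (0.0506) and mitochondrial ribosome (0.0045). Under TPM scaling the direction turned for Per1 (5.00e-04), and for the lists mitochondrial ribosome (8.78e-04) and theca and stroma markers (0.1151). Under median-of-ratios scaling, with or without the block, the direction turned for Csnk1d (-0.0098), Mrpl34 (-0.0564), Pnpla2 (-0.0227) and Cdkn1a (-0.0043), and for the lists mitochondrial biogenesis regulators (-0.0516), nuclear respiratory chain and ATP synthase subunits (-0.0546) and fatty acid oxidation (-0.0197). Under quantile normalization, with or without the block, the direction turned for Hsd3b1 (0.1662) and Sparc (0.0379), and for the list mitochondrial biogenesis regulators (-0.0078). With sample weights the direction turned for Clock (-0.0069), Per1 (0.0367), Timm23 (0.009), Ptges (0.0439), Ifitm3 (0.0521), Nrf1 (0.0071) and Gm23935 (-0.1991), and for the lists genes repressed by REV-ERB proteins in other tissues (-0.0069), mitochondrial ribosome (0.0037), interferon-stimulated genes (0.0521) and theca and stroma markers (0.1074). Without both replicate 1 libraries, with or without the block, the direction turned for Clock (-0.0213), Per1 (0.0711), Timm23 (0.0275), Ptges (0.085), Ifitm3 (0.1437), Star (-0.1222), Nrf1 (0.0077) and Gm23935 (-0.6416), and for the lists genes repressed by REV-ERB proteins in other tissues (-0.0213), granulosa cell identity and hormone receptors (0.0092), interferon-stimulated genes (0.1437), xenobiotic metabolism (-0.0051) and theca and stroma markers (0.1901). In voom the direction turned for Mrpl34 (-0.0027). In voom with the block the direction turned for Mrpl34 (-0.0025). With each replicate left out in turn, the log2 changes ran as follows for genes that turned in at least 1 of them: Timm23 -0.0897 to 0.0747, Cdc20 -1.2576 to 0.0555, Ccnb2 -1.1918 to 0.0799, Ptges -0.1786 to 0.2457, Ifitm3 -0.2537 to 0.0824, Fosl2 -0.1155 to 0.3221, Gstm1 -0.2138 to 0.9048, Col1a1 -0.6263 to 0.2481, Gm23935 -0.6587 to 1.1018, Per2 -0.1408 to 0.0463, Hsd3b1 -0.5129 to 0.3514 and Mrpl34 -0.0671 to 0.1291. For the others of these genes they were Me1 -0.3763 to 0.0747, Pnpla2 -0.0713 to 0.1141, Pcna -0.166 to 0.3444, Axl -0.0567 to 0.2013, Acta2 -0.3032 to 0.8831, Nrf1 -0.0746 to 0.0347, Per1 -0.0555 to 0.0783, Cdkn1a -0.0474 to 0.1468, Lyz2 -0.1943 to 1.1722, Clock -0.0217 to 0.1763, Scd2 -5.76e-04 to 0.2495 and Sparc -0.0962 to 0.0061. List medians that turned ran as follows: mitochondrial biogenesis regulators -0.0013 to 0.0382, mitochondrial ribosome -0.0561 to 0.0352, fatty acid and triglyceride synthesis -0.0297 to 0.0363, mitosis -1.1278 to 0.0725, DNA replication -0.6237 to 0.0154, collagens and extracellular matrix -0.3304 to 0.0715, TGF-beta and YAP targets -0.3072 to 0.1278 and interferon-stimulated genes -0.1864 to 0.0824. The others were xenobiotic metabolism -0.019 to 0.2758, theca and stroma markers -0.1829 to 0.2818, inflammatory cytokines and chemokines -0.0042 to 0.1163, nuclear respiratory chain and ATP synthase subunits -0.0403 to 0.0512 and genes repressed by REV-ERB proteins in other tissues -0.0217 to 0.1306.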

Other observations

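Of the tests reported here, those of nuclear copies, scaling and a single factor for mitochondrial mRNAs, of control replicate 2 and other cells for glycolysis, and of leukocytes, of genes outside the other lists and of scaling of the 61 unseen genes for lysosomal genes were chosen after the result was seen; the splits of the samples, the lysosomal genes not seen before and the scaling of the whole lysosomal list were set before it. The genes named in this part were chosen after their values were seen. Several genes of lysosomes were higher with GSK4112. As a set, the 61 unseen genes were not called in camera with an estimated correlation (adjusted p = 0.5054). Mcoln1, a lysosomal calcium channel, rose from 8.57 ± 0.334 to 14.7 ± 0.799 FPKM (log2 change 0.71 ± 0.0793 SE, adjusted p = 0.0224 in limma, 3 of 3 pairs higher). Rragd (10.1 ± 1.15 to 18.4 ± 0.879, adjusted p = 0.0341) and Flcn (9.09 ± 1.69 to 17.2 ± 1.14, 0.0477), which act in nutrient sensing at the lysosome, also rose. The protease gene Ctsl was called with the block (148 ± 5 and 391 ± 111, 0.0507 without and 0.0107 with it), while Psap, the precursor of saposins, was at 644 ± 20.7 and 975 ± 47.3 (0.061 and 0.0587). The ferritin genes, which store iron, were at 152 ± 25.6 and 255 ± 14.5 for Ftl1 (0.0641 without and 0.0262 with the block) and at 779.5 ± 105 and 1304 ± 98.6 for Fth1 (0.0734 and 0.0581).

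Beside Kitl on chromosome 10, the long noncoding RNA gene Gm35533 (chromosome 10, 100129868 to 100144126, minus strand) rose from 25.2 ± 6.37 to 238 ± 124 FPKM (adjusted p = 0.0384 in limma), the largest rise of all called genes. Gm22918, which lies inside it on the other strand (67.8 ± 24.2 and 609 ± 339.9, 0.0676 without and 0.0223 with the block), and Gm25287, which lies just beyond it (0.676 ± 0.762 and 56.4 ± 40.1, 0.0521 and 0.0191), are annotated as microRNA genes. Values of overlapping genes cannot be told apart here. Mamdc2, which encodes a secreted protein, was at 20.8 ± 8.59 and 122 ± 57.2 (0.0734 without and 0.0018 with the block). Ahrr, the repressor of the aryl hydrocarbon receptor, was at 0.901 ± 0.058 and 2.23 ± 0.364 (0.0668 and 0.0256), while Ahr itself fell. The stress genes Ddit3 (9.54 ± 1.87 and 19.2 ± 2.92, 0.0591 and 0.0051) and Chac1 (4.12 ± 0.929 and 9.44 ± 1.803, 0.0621 and 0.0053) were called as higher with the block. Igf1 (24.8 ± 6.74 and 12.4 ± 3.83, 0.1342 and 0.0076) and Akr1c18, which breaks down progesterone (14.9 ± 8.59 and 3.15 ± 1.46, 0.1631 and 0.0063), were called as lower with it. The real split gave 126 genes and the highest of the other 9 splits 0, so 1 of 10 splits gave as many; with the block it was 839 against 0 in the other 3 splits that part all 3 pairs, 1 of 4. These splits are too few for a share under 0.05. For lists, 6 of 10 splits gave as many as the real 13, with up to 19 in another split.

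The mRNAs of the mitochondrial genome were lower with GSK4112 (median -0.36), though not called with an estimated correlation (adjusted p = 0.6557) or in fry with the block (0.0774). Reads shared with near-identical nuclear copies would leave members without such copies unchanged. But the 4 members with under 50% of their length in such a match had a median of -0.36 (median of their single-gene SEs 0.1492). The 3 with no such match had one of -0.3731. Under 4 other scalings the list median was at most -0.304, which argues against scaling between libraries. The list also stayed called in camera under them. That adds little, since camera sets a list against all other genes and a factor for a whole library moves both. A single factor for all of these mRNAs stays open: the log2 ratio of mt-Co1 to those 4 members was 0.43 higher with GSK4112, but mt-Co1 was picked because it had not fallen and matches a nuclear transcript over its length, at 97.605% identity, so this decides nothing. A treatment effect on mitochondrial RNA may account for the fall and stays a hypothesis. The medians of the other 9 splits ran from -0.1523 to 0.1843. Their sign only marks which side was subtracted, and it was positive where that side held most of the GSK4112 libraries.

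Glycolysis and hypoxia genes were lower with GSK4112, and 23 of 26 were highest in control replicate 2, by a median of 3.29-fold over the other control libraries. Ldha, lactate dehydrogenase, was at 750.2 FPKM there against 151 and 138 in the other control libraries. Without that library the median moved from -0.71 to -0.16 (adjusted p = 0.0047 in camera), so control replicate 2 may account for most of its size; with an estimated correlation the list was not called in the full data (adjusted p = 0.8826). Other cells in that library stay open, since over 3 marker lists the highest ratio of its summed FPKM to the lower of the other controls was 1.64, though no list was above both. A lower oxygen supply in that culture and an effect of GSK4112 stay open and were not tested.

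A list of 70 lysosomal genes was written after 9 of them had been seen. The 61 not seen before had a median of 0.25, 55 were above control, and camera gave an unadjusted p = 2.29e-09 and fry 0.003; with an estimated correlation it was 0.0446 unadjusted, but 0.5054 adjusted with the 33 lists; 1 was called and 10 with the block, all higher; without 3 that also belong to a list tested before, 58 remain, with a median of 0.24 and an unadjusted p = 6.16e-09. A choice of genes already seen to rise thus does not account for the shift in camera. Yet other splits gave medians of -0.1519 to 0.0859, with camera p down to 3.44e-07. Their sign only marks which side was subtracted, and it was negative where that side held most of the GSK4112 libraries. In each of these splits the median was thus higher on the side with more GSK4112 libraries. The splits reuse the same libraries, so this direction largely follows from the real difference and is no separate support for it. Under 4 other scalings the median of all 70 was at least 0.2467, against 0.3033 as deposited, and that of the 61 at least 0.1909; leukocyte markers were 4.24 summed FPKM higher against 1123.5 for the 70 genes and 452.7 for the 61, under the tenth set, somewhat arbitrarily, as the bound for more leukocytes. An effect of GSK4112 on lysosomal genes may be the source and stays a hypothesis.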
